A study of Arabidopsis thaliana with 15 samples.

How the data were processed

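The series holds 15 mRNA-seq libraries of whole Arabidopsis thaliana seedlings, 3 biological repeats each of WT, emf1, lhp1, the double mutant ebs shl and the triple mutant ebs shl lhp1. Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument. RNA was isolated with the RNeasy Plus Mini kit from WT, lhp1 and ebs shl and with the miRNeasy Micro kit from emf1 and ebs shl lhp1. The deposited values are counts of reads per annotated locus, 1 file per library with 33602 loci. Per the submitters' processing notes, TopHat2 2.1.1, HTSeq and edgeR were used with the TAIR10 build, without versions of the last 2 tools and without the strand setting of the counting. All 279 chloroplast and mitochondrial loci had 0 counts in every library, so a fit without organelle genes gave the same values. The annotation at hand, TAIR10.1, is not the build of the counts, so gene names, gene order, GC content and exon length were taken from it and no coordinates are given. Of the tested loci 20457 were matched to it.

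Library totals were 11730989 to 16247262 counts. A single count was 0.0852 CPM in the smallest and 0.0615 CPM in the largest library. Repeats correlated at r of 0.972 to 0.990 on the log scale, and pairs of repeats differed by 4.33 to 25.3 chi-square units per degree of freedom, where counting alone gives 1. By genotype this was 8.25 to 20.2 in WT, 4.93 to 9.94 in lhp1, 4.33 to 9.27 in ebs shl, 15.2 to 25.3 in ebs shl lhp1 and 17.8 to 20.9 in emf1. The fit below took 1 spread per gene over all genotypes. Its tests may be too lenient where repeats differed more and too strict where they differed less. The common biological coefficient of variation was 16.3%.

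Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The filterByExpr function kept 20477 loci, and 4571 had no count anywhere. All 15 libraries were scaled with TMM factors (0.817 to 1.146) and fitted together, with 1 mean per genotype. Changed genes are those with an adjusted p under 0.05 in edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment. The SE of a log2 fold change was taken from the fold change and its F value. There were 6 comparisons, namely each of the 4 mutants against WT, ebs shl lhp1 against emf1, and the interaction, which is the difference between ebs shl lhp1 and ebs shl minus that between lhp1 and WT. Where the lower group held no count, the ratio is given as at least the value at a floor of 3 counts over the 3 libraries of that group together, and where it held 1 to 3 counts, the ratio is followed by its exact 95% counting interval, which covers counting error only.

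Lists of 259 genes in 15 groups were fixed before the data were examined: Polycomb group components, floral organ and floral meristem identity, flowering time, embryo and seed maturation regulators, seed storage and late embryogenesis, KNOX, WOX and meristem genes, photosynthesis, abscisic acid with cold and drought, salicylic acid and defence, jasmonate, touch and wounding, flavonoid and anthocyanin, root tissue markers, anther and tapetum markers, and reference genes. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Only members that passed the filter were tested. Numbers kept included 7 of 21 seed storage genes, 4 of 17 anther markers, 6 of 12 embryo regulators and 14 of 20 floral identity genes. The filter could keep a gene with counts in 1 mutant only, which can appear there as a rise but not as a fall. Adjusted p of lists are adjusted over the 15 lists of a comparison. Where a list's counts are given once, those adjusted over the list alone were the same. Morning and evening clock genes, dark and sugar starvation genes, nuclear ribosomal RNA, root hair and root endodermis genes were added after the data were seen. Named genes followed a rule fixed beforehand. It took the 4 mutated genes in every library. It took the 8 highest and 8 lowest log2 fold changes per comparison (5 and 5 for the last 2 comparisons) among called genes with at least 5 CPM in the higher group, groups that did not overlap (not asked of the interaction) and a known symbol. Last, it took up to 4 called members per list by size of change, or its most abundant member if none was called. Other genes named were chosen after their values were seen.

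Of 171 genes that met the rule, 27 overlap a tested gene on the opposite strand, and their levels are uncertain because the strand setting is not known. Of those in the text these are LHP1, SEP1, RAB18, LHCB1.3, DREB2A, EDS5, BCAT2, CLF, WRKY40, DTX1, RCA and SERAT3;2. A near-identical copy (95% identity over 50% of the length, BLAST 2.17.0) makes the levels of LHCB1.3 and VIM4 uncertain.

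The same fit was tested on simulated counts with 200 genes changed by known ratios (199 of those passed the filter for ebs shl lhp1 against emf1). Of genes changed 2-fold and 4-fold it recovered 69% and 97% for lhp1 (20320 genes), 67% and 94% for ebs shl (20243), 64% and 94% for ebs shl lhp1 (20187), 66% and 92% for emf1 (20191), 65.7% and 89% for ebs shl lhp1 against emf1 (20262) and 41% and 86% for the interaction (20292). False calls made up 6.21%, 4.17%, 0%, 6.51%, 3.75% and 4.51% of the calls. Beyond the changed genes nothing differed in the comparison tested, and those genes went up and down in equal numbers. These rates therefore do not cover comparisons in which most genes were called. Overlaps of calls were set against 20 simulated data sets in which no gene differed.

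Alternatives fixed beforehand were DESeq2 size factors (RLE) and upper-quartile factors in place of TMM, no filter on low counts, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and each library left out in turn. After the data were seen, fits without the 4 nuclear ribosomal RNA loci and with offsets for GC content and exon length (known for 20457 genes) were added.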

Results

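Messenger RNA was sequenced from whole Arabidopsis thaliana seedlings of the Col-0 accession. They had grown for 3 weeks on diluted Murashige and Skoog medium in short days of 8 h light and 16 h dark. The 5 genotypes were wild type (WT), emf1, lhp1, the double mutant ebs shl, and the triple mutant ebs shl lhp1. With 3 biological repeats each, there were 15 libraries. LHP1 is a chromodomain protein that binds the Polycomb mark H3K27me3. EBS and SHL are a pair of related proteins that bind histone H3 marks including H3K27me3, and EMF1 is a plant protein that acts with Polycomb complexes. The deposited gene counts summed to between 11730989 and 16247262 per library, and 20477 nuclear genes had enough counts to be tested. Levels are given as normalised CPM, as the mean ± SD of the 3 libraries of a genotype. RNA of WT, lhp1 and ebs shl was isolated with one kit and RNA of emf1 and ebs shl lhp1 with another, so that a comparison across the kits does not by itself separate the kit from the genotype. Below, the libraries labelled ebs shl and ebs shl lhp1 are called the labelled double mutant and the labelled triple mutant, and emf1 and lhp1 stand for the libraries with those labels.

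Along the first principal component, which held 69.3% of the variance of log CPM, the 3 libraries of the labelled triple mutant and the 3 of emf1 lay apart from the 9 libraries of WT, lhp1 and the labelled double mutant. The second component held 13.1% and separated the libraries of the labelled triple mutant from those of emf1. Nuclear ribosomal RNA took 0.294% ± 0.0684 of the counts in WT, 0.266% ± 0.0589 in lhp1 and 0.264% ± 0.0594 in the labelled double mutant (SD, n = 3 each). In the labelled triple mutant it took 1.40% ± 0.366 and in emf1 0.703% ± 0.118 (SD, n = 3 each).

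**Figure D1:**
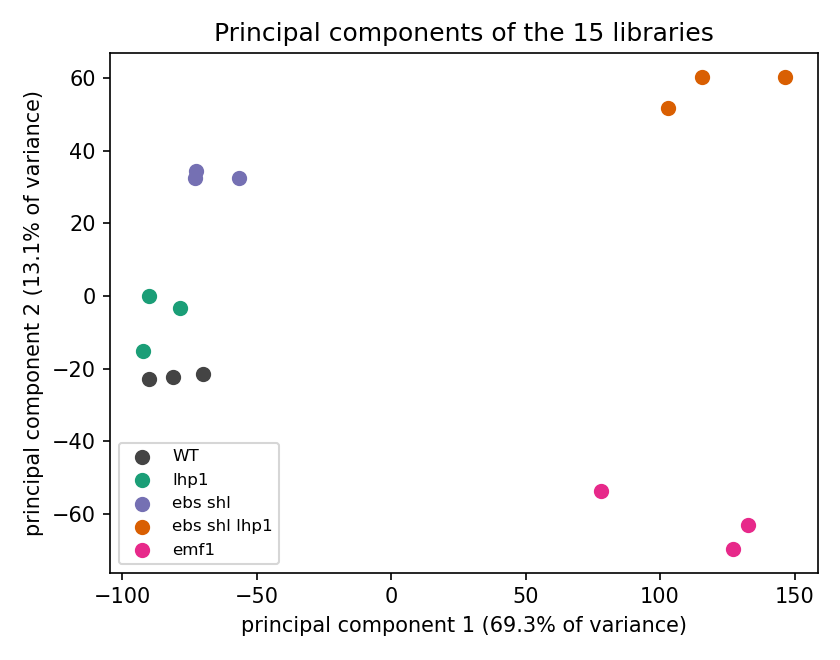
Each point is 1 of the 15 libraries, placed by the first (x axis) and second (y axis) principal component of its log CPM values and coloured by genotype. The 6 libraries of the labelled triple mutant and emf1 lie on the right and the other 9 on the left, a split that is also the split between the RNA kits.

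The transcripts of the mutated genes were examined first in every library. LHP1 (AT5G17690) stood at 19.8 ± 1.15 CPM in WT and 10.5 ± 0.384 in lhp1 (SD, n = 3), a fall of 1.89-fold, with 10.1 to 10.8 CPM in the 3 lhp1 libraries against 18.6 to 20.8 in WT. In the labelled triple mutant it stood at 21.1 ± 2.07 CPM, with 19.3 to 23.4 in single libraries, and did not differ from WT (log2 fold change 0.09, SE 0.09; adjusted p = 0.39 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In emf1, with the RNA kit of the labelled triple mutant, LHP1 stood at 26.3 ± 1.34 CPM, with 25.3 to 27.8 in single libraries. This was above WT (log2 fold change 0.41, adjusted p = 0.0013, edgeR quasi-likelihood) and above each library of the labelled triple mutant. EBS (AT4G22140) fell from 25.8 ± 1.65 CPM in WT to 2.54 ± 0.846 in the labelled double mutant and 2.28 ± 0.262 in the labelled triple mutant. SHL (AT4G39100) rose from 41 ± 2.77 CPM in WT to 217 ± 11.3 in the labelled double mutant and 191 ± 31 in the labelled triple mutant. It was also above WT in emf1, at 68.4 to 80.6 CPM in single libraries (log2 fold change 0.88, adjusted p = 2.1e-05, edgeR quasi-likelihood). EMF1 (AT5G11530) stood at 28 ± 0.641 CPM in WT and 22.8 ± 1.09 in emf1, at 46.2 ± 3.07 in lhp1, at 118 ± 2.48 in the labelled double mutant, a rise of 4.22-fold, and at 77.6 ± 8.3 in the labelled triple mutant, a rise of 2.75-fold. The lower EMF1 value in emf1 (adjusted p = 0.0073, edgeR quasi-likelihood) lost its call without WT replicate 2 (adjusted p = 0.0998) and under an offset for GC content and gene length (adjusted p = 0.957). Transcript levels were therefore lower than in WT, where the labels name the mutation, for EBS and for LHP1 in the single mutant. They were not lower for LHP1 in the labelled triple mutant or for SHL. For EMF1 in emf1 transcript levels did not check the label. The labels give no alleles, so a transcript that is not lowered does not show that the mutation is absent. LHP1 overlaps a gene on the other strand and its level is uncertain, because the strand setting of the counting was not stated.

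**Figure D2:**
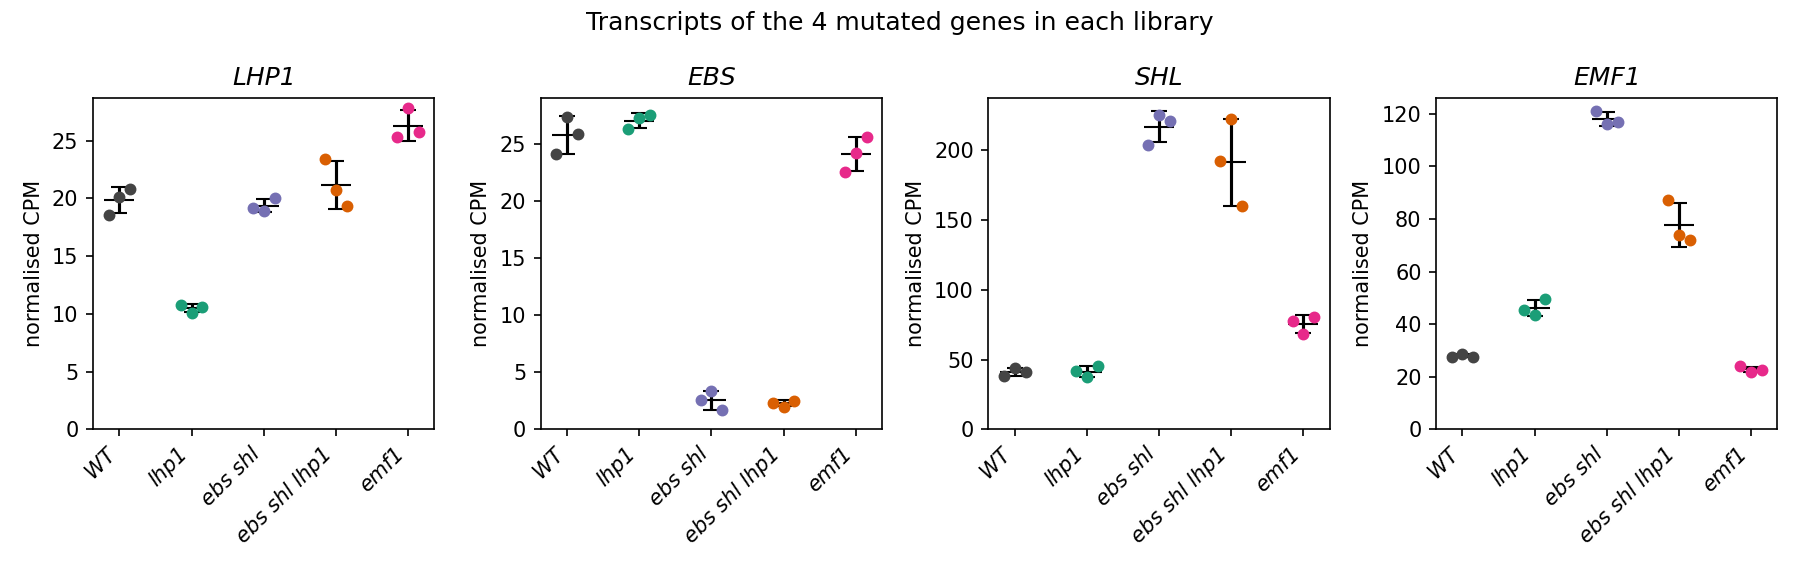
Normalised CPM (y axis) of LHP1, EBS, SHL and EMF1 in each of the 3 libraries per genotype (x axis), with the mean (horizontal line) and SD (error bar). LHP1 is at 10.5 CPM in lhp1 and 21.1 in the labelled triple mutant, EBS is below 4 CPM in the labelled double and triple mutants, and SHL is at 217 and 191 CPM there against 41 in WT.

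The comparison of lhp1 with WT asked which transcripts differ in lhp1, and floral identity genes rose in these seedlings. AG (AT4G18960), the class C floral organ gene, rose from 0.0824 CPM in WT to 22.9 ± 2.76 in lhp1 (SD, n = 3), a ratio of 278-fold. The class B gene AP3 (AT3G54340) stood at 0.0614 CPM in WT and 16.5 ± 2.02 in lhp1, 267-fold [counting interval 91 to 1300]. The class E genes SEP1 (AT5G15800), SEP2 (AT3G02310) and SEP3 (AT1G24260) reached 34.1 ± 3.07, 8.87 ± 0.264 and 133 ± 9.88 CPM, which was 104-fold, 216-fold [counting interval 59.5 to 1790] and 99.6-fold the WT level. Of 14 tested genes for floral organ and floral meristem identity, 12 rose and 0 fell (14 and 0 adjusted over the list alone). The list as a whole lay above the other genes (camera adjusted p = 3.8e-97, and adjusted p = 1.1e-05 with an estimated correlation). Members near 0 counts in WT, such as AG and AP3, could show only as rises, here and in the other comparisons with WT. The 0 that fell says nothing about them, and part of the list's call may follow from the filter. The same holds for seed storage genes near 0 counts in WT.

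Among 22 tested flowering time genes, 5 rose and 2 fell in lhp1 (6 and 4 adjusted over the list alone; camera adjusted p = 0.00025, and adjusted p = 0.016 with an estimated correlation). The MADS-box genes AGL24 (AT4G24540) and AGL42 (AT5G62165) rose from 7.01 ± 1.16 to 25 ± 2.5 CPM and from 1.18 ± 0.211 to 4.8 ± 0.174. FT (AT1G65480), the florigen gene, rose from 0.0411 to 1.5 ± 0.746 CPM, 37.2-fold [counting interval 9.92 to 313]. Its call (adjusted p = 0.028, edgeR quasi-likelihood) was lost without WT replicate 1, 2 or 3 and without lhp1 replicate 1 or 2, with adjusted p of 0.0554 to 0.144. Outside these lists, the sugar transporter gene SWEET10 (AT5G50790) rose from 0.204 to 14.1 ± 1.35 CPM and the transcription factor gene GATA13 (AT2G28340) from 0.144 to 8.82 ± 0.705. The largest falls included QQS (AT3G30720), a gene tied to starch content, from 8.6 ± 1.07 to 0.484 ± 0.152 CPM (18-fold), and the YABBY gene YAB5 (AT2G26580), from 14.3 ± 2.19 to 1.86 ± 0.349 (7.73-fold). DCF (AT3G48720) fell from 25.3 ± 1.84 to 3.32 ± 0.597 CPM, the methionine sulfoxide reductase gene MSRB6 (AT4G04840) from 86.4 ± 6.25 to 14.7 ± 3.91, and the jasmonate biosynthesis gene AOC2 (AT3G25770) from 45.1 ± 16.1 to 10.1 ± 2.49. The bHLH gene KDR (AT1G26945) fell 4.2-fold.

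Of 7 tested genes for seed storage and late embryogenesis, 1 rose and 0 fell in lhp1 (3 and 0 adjusted over the list alone; camera adjusted p = 0.00033, and adjusted p = 0.028 with an estimated correlation). It was RAB18 (AT5G66400), a dehydrin gene, at 12.9 ± 4.77 CPM in WT and 39.5 ± 6.92 in lhp1. The 36 photosynthesis genes had 0 members past the threshold over all genes, yet 0 rose and 21 fell when adjusted over the list alone. Their median log2 fold change was -0.30 (camera adjusted p = 2.1e-12), a call lost with an estimated correlation (adjusted p = 0.40 with an estimated correlation). The most abundant of them, LHCB1.3 (AT1G29930), stood at 19200 ± 209 CPM in WT and 15700 ± 1180 in lhp1. Of 12 salicylic acid and pathogen defence genes, 0 rose and 1 fell (camera adjusted p = 0.0068, and adjusted p = 0.14 with an estimated correlation). The fallen gene, PR5 (AT1G75040), lost its call in each of the 6 fits without 1 WT or lhp1 library (adjusted p of 0.0608 to 0.186). None of the 8 touch and wounding, 18 root, 6 reference, 13 flavonoid, 11 meristem, 7 jasmonate, 4 anther or 17 Polycomb genes passed the threshold over all genes in lhp1. Adjusted over the list alone, 2 meristem genes, 1 flavonoid gene and 2 jasmonate genes were higher and 1 root and 1 jasmonate gene lower. The drought gene RD22 (AT5G25610) was the 1 of 19 abscisic acid, cold and drought genes that did, and fell from 405 ± 16.5 to 178 ± 8.86 CPM (1 higher and 2 lower over the list alone).

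In total 269 of 20477 genes changed in lhp1 at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg), 158 higher and 111 lower. Of these, 191 changed by at least 1 on the log2 scale (126 higher and 65 lower). In 20.4% of all tested genes the 3 lhp1 libraries did not overlap the 3 WT libraries, where chance gives 10%. The count was 209 without WT replicate 1, 151 without WT replicate 2 and 144 without WT replicate 3, and 153, 165 and 162 without lhp1 replicates 1, 2 and 3. It was 471 when only these 2 genotypes were fitted and 507 with DESeq2. The balance of directions was not stable, with 99 higher and 110 lower without WT replicate 1 and 255 and 252 with DESeq2.

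**Figure D3:**
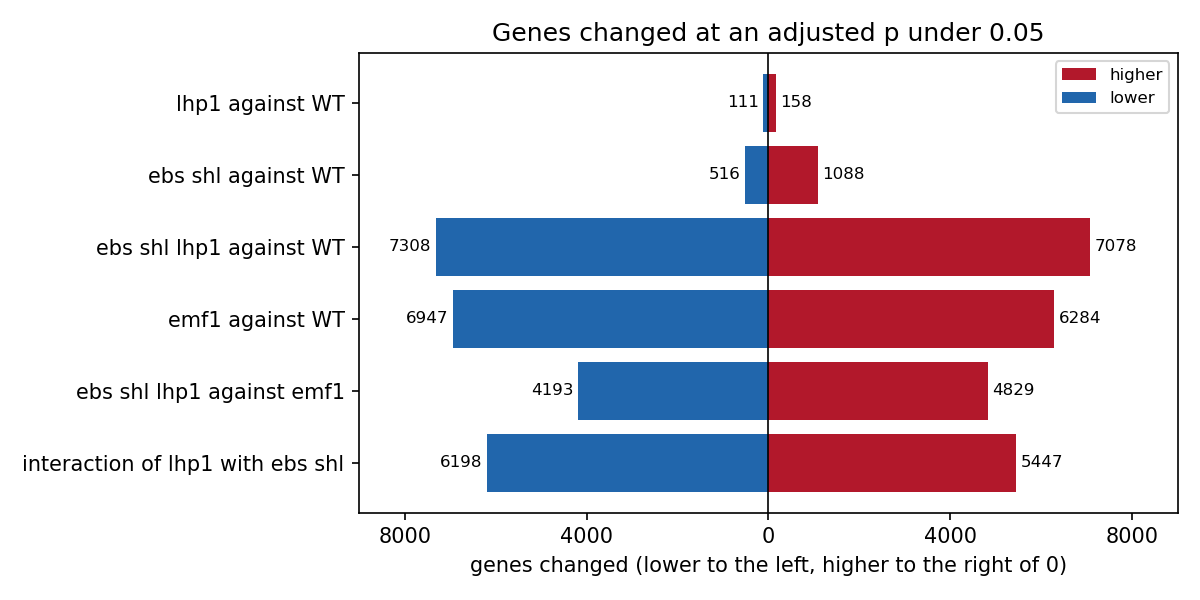
Bars give the number of genes with an adjusted p under 0.05 (edgeR's quasi-likelihood test) that were higher (right of 0) or lower (left of 0) in each of the 6 comparisons. The counts run from 269 genes in lhp1 to 14386 in the labelled triple mutant, with 20477 genes tested in each.

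The comparison of the labelled double mutant with WT asked which transcripts differ in seedlings with this label, in which EBS was low and SHL above WT. Floral identity genes rose here too, and all 14 tested members passed the threshold. The meristem identity gene AP1 (AT1G69120) stood at 0.0204 CPM in WT and 11.3 ± 1.96 in the labelled double mutant (SD, n = 3), 546-fold [counting interval 97.5 to 21600]. AP3 reached 18.5 ± 2.92 CPM, SEP1 39.7 ± 7.83, SEP2 7.84 ± 1.59 and SEP3 117 ± 15.2, while AG reached 3.57 ± 1.53, below its level in lhp1. The class B gene PI (AT5G20240) stood at 3.09 ± 0.608 CPM in WT, 19.1 ± 3.95 in lhp1 and 80.9 ± 8.48 in the labelled double mutant. The list lay above the other genes (14 rose and 0 fell over all genes and over the list alone; camera adjusted p = 2.4e-69, and adjusted p = 5e-05 with an estimated correlation).

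Of the 22 flowering time genes, 9 rose and 2 fell in the labelled double mutant (12 and 2 adjusted over the list alone; camera adjusted p = 8.9e-10, and adjusted p = 0.00052 with an estimated correlation). FT stood at 2.15 ± 0.609 CPM, AGL24 at 35.6 ± 2.94 and AGL42 at 9.67 ± 0.872, each above WT. Of 11 tested KNOX, WOX and meristem genes, 7 rose and 0 fell (7 and 2 adjusted over the list alone; camera adjusted p = 1.4e-05, and adjusted p = 0.012 with an estimated correlation). The organ boundary genes CUC1 (AT3G15170), CUC2 (AT5G53950) and CUC3 (AT1G76420) rose to 2.33 ± 0.128, 4.13 ± 0.183 and 4.21 ± 0.73 CPM from 0.37, 0.822 and 0.983 in WT. The homeobox gene KNAT6 (AT1G23380) rose from 6.94 ± 0.306 to 17.2 ± 1.89. Of 7 seed storage and late embryogenesis genes, 3 rose and 0 fell (3 and 0 over the list alone; camera adjusted p = 1.4e-05, and adjusted p = 0.009 with an estimated correlation). Among them the vicilin-like storage protein gene PAP85 (AT3G22640) rose from 0.0822 to 11.6 ± 3.21 CPM (141-fold). The late embryogenesis gene M17 (AT2G41260) rose from 0.308 to 16.5 ± 1.66 (53.7-fold). Of 6 embryo and seed maturation regulators, 0 rose and 2 fell, the MADS-box genes AGL15 (AT5G13790) and AGL18 (AT3G57390) (0 and 2 over the list alone; camera adjusted p = 0.00072), a call lost with an estimated correlation (adjusted p = 0.05 with an estimated correlation). AGL18 stood at 11.4 ± 0.312 CPM in WT and 3.54 ± 0.441 in the labelled double mutant.

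The late-step anthocyanin enzyme genes DFR (AT5G42800) and LDOX (AT4G22880) fell in the labelled double mutant, from 10.6 ± 2.25 to 0.548 ± 0.0703 CPM and from 11.9 ± 4.2 to 1.13 ± 0.446. Of the list, 5 of 13 flavonoid and anthocyanin genes fell and 0 rose (7 and 0 adjusted over the list alone). The list's call (camera adjusted p = 4e-06) was lost with an estimated correlation (adjusted p = 0.10 with an estimated correlation). The jasmonate-responsive storage protein genes VSP1 (AT5G24780) and VSP2 (AT5G24770) rose to 22.2 ± 2.92 and 70 ± 11.9 CPM from 4.01 ± 0.286 and 6.02 ± 3.52. Of 7 jasmonate genes 2 rose and 1 fell (camera adjusted p = 0.23). Of 19 abscisic acid, cold and drought genes 1 rose, the transcription factor gene DREB2A (AT5G05410) (4.76 ± 2.92 to 34.5 ± 2.94 CPM). Of the same list 3 fell, with RD22 at 175 ± 13.8 CPM. Of 12 salicylic acid genes, EDS5 (AT4G39030) fell, from 10.2 ± 2.47 to 1.64 ± 0.287 CPM. EDS5 lies 6 tested genes from SHL, in the block of neighbouring genes with more calls than chance. Other large rises were those of VIM5 (AT1G57800), of a family that binds methylated cytosine, to 11 ± 1.2 CPM (266-fold [counting interval 73.2 to 2200]), and the receptor-like kinase gene CRK4 (AT3G45860), from 0.551 ± 0.421 to 36.2 ± 4.55. The largest falls included QQS (40.9-fold), the receptor-like kinase gene SRF8 (AT4G22130) (40.8 ± 1.76 to 2.43 ± 0.205 CPM), whose locus number is next to that of EBS, YAB5 (9.18-fold) and the brassinosteroid-responsive gene BEE3 (AT1G73830) (23 ± 8.74 to 2.57 ± 0.973 CPM).

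In the labelled double mutant 1604 genes changed, 1088 higher and 516 lower (edgeR quasi-likelihood, adjusted p under 0.05), and 907 by at least 1 on the log2 scale (706 higher and 201 lower). The groups did not overlap in 30.6% of genes, against 10% by chance. Without WT replicates 1, 2 and 3 the count was 1119, 1084 and 1007, and without labelled double mutant replicates 1, 2 and 3 it was 1044, 1045 and 950. The photosynthesis list was called lower (camera adjusted p = 0.00035; 0 rose and 1 fell, and 0 and 0 over the list alone), a call lost with an estimated correlation (adjusted p = 0.62 with an estimated correlation), while the touch, root, anther and reference lists had 0 called members.

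**Figure D4:**
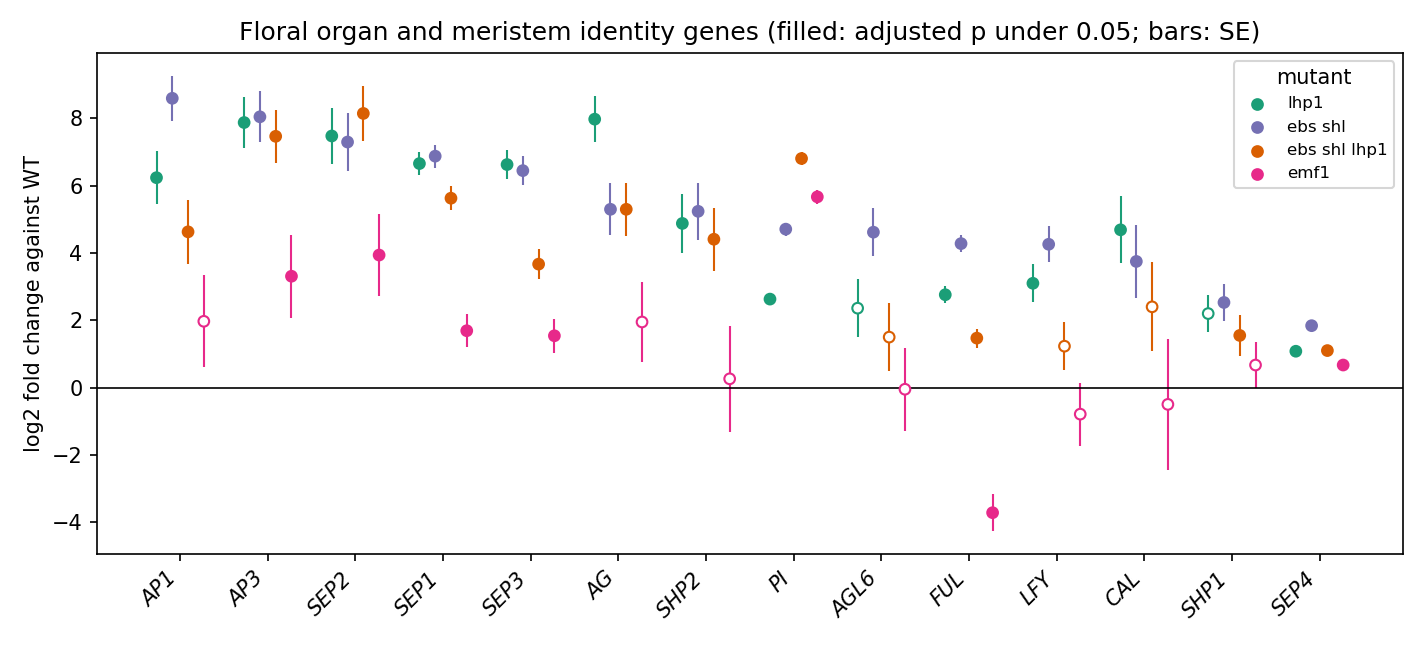
Log2 fold change against WT (y axis, points; bars are the SE) of the 14 tested floral organ and meristem identity genes (x axis) in each of the 4 mutants, with 3 libraries per genotype. Filled points have an adjusted p under 0.05; 12 points are filled for lhp1, 14 for the labelled double mutant, 11 for the labelled triple mutant and 7 for emf1, where FUL is below 0.

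The comparison of the labelled triple mutant with WT asked which transcripts differ in seedlings with this label, and most measured genes did. LHP1 was at the WT level and SHL above it. PI reached 347 ± 39.5 CPM against 3.09 ± 0.608 in WT (SD, n = 3), a ratio of 110-fold. SEP2 reached 14.2 ± 5.4, while SEP3 stood at 17.2 ± 12.5 and AG at 3.57 ± 2.69, both below their lhp1 level. The flowering repressor gene FLC (AT5G10140) rose from 5.88 ± 1.3 to 48.9 ± 20.3 CPM. By edgeR's quasi-likelihood test FLC was also above WT in the labelled double mutant (log2 fold change 1.3, adjusted p = 0.007) and in emf1 (1.42, adjusted p = 0.00037). In lhp1 it did not pass (1.14, adjusted p = 0.058, edgeR quasi-likelihood). Seed genes that rose included M17 (82.1 ± 16.4 CPM, 263-fold) and PAP85 (12 ± 0.631 CPM). The late embryogenesis gene EM1 (AT3G51810) had no count in WT and stood at 2.29 ± 1.35 CPM, at least 37.5-fold higher. Genes that fell included the root iron transporter gene IRT1 (AT4G19690), from 27.8 ± 13.4 to 0.19 ± 0.186 CPM (145-fold) and the arabinogalactan protein gene AGP30 (AT2G33790) from 6.21 ± 1.09 CPM to no count (at least 75.6-fold lower).

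By list, 11 of 14 floral identity genes rose and 0 fell in the labelled triple mutant (11 and 0 adjusted over the list alone). The camera call (adjusted p = 3.4e-05) was lost with an estimated correlation (adjusted p = 0.28 with an estimated correlation). Of 22 flowering time genes 12 rose and 2 fell (12 and 2 over the list alone; camera adjusted p = 0.14), and 9 rose and 2 fell under upper-quartile scaling. Of 7 seed storage and late embryogenesis genes 6 rose and 1 fell (6 and 1 over the list alone; camera adjusted p = 0.032, and adjusted p = 0.28 with an estimated correlation). All 13 flavonoid and anthocyanin genes fell (13 over the list alone; camera adjusted p = 0.003, and adjusted p = 0.33 with an estimated correlation). LDOX stood at 0.053 CPM, 215-fold [counting interval 59.3 to 1780] lower, DFR at 0.248 ± 0.191, and the flavonol synthase gene FLS1 (AT5G08640) at 3.6 ± 1.14 against 39.9 ± 14.1 in WT. Of 18 root tissue markers 15 fell and 1 rose (16 and 1 over the list alone; camera adjusted p = 0.0039, and adjusted p = 0.33 with an estimated correlation). The root hair gene LRX1 (AT1G12040) went from 6.67 ± 2.08 to 0.208 ± 0.282 CPM and the ferric reductase gene FRO2 (AT1G01580) from 13.7 ± 6.53 to 0.531 ± 0.116.

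Of the 8 touch and wounding genes 7 rose and 0 fell in the labelled triple mutant (8 and 0 over the list alone; camera adjusted p = 0.14). The calmodulin-like gene TCH3 (AT2G41100) stood at 50.9 ± 51 CPM in WT and 476 ± 220 here, and the transcription factor gene WRKY40 (AT1G80840) at 1.99 ± 0.891 and 57.7 ± 66.7, a wide spread between libraries. Of 36 photosynthesis genes 19 fell and 0 rose (19 and 0 over the list alone; camera adjusted p = 0.059). The Rubisco small subunit gene RBCS2B (AT5G38420) fell from 2650 ± 287 to 851 ± 164 CPM. Of 17 Polycomb group genes 5 rose and 7 fell (5 and 7 over the list alone; camera adjusted p = 0.88), and 3 rose and 7 fell under upper-quartile scaling. The histone methyltransferase gene CLF (AT2G23380) fell from 29.9 ± 2.14 to 12.6 ± 1.38 CPM. Of 11 meristem genes 5 rose and 3 fell (camera adjusted p = 0.97), with the root stem cell genes PLT1 (AT3G20840) and PLT2 (AT1G51190) lower, at 0.279 ± 0.184 and 0.053 CPM against 2.96 ± 0.957 and 2.67 ± 0.863. The list's median log2 fold change was 0.50 and its mean -0.40, and 3 rose and 3 fell under upper-quartile scaling. Of 12 salicylic acid genes 3 rose and 6 fell (camera adjusted p = 0.22), and of 19 abscisic acid, cold and drought genes 6 rose and 6 fell (camera adjusted p = 0.97; median -0.52 and mean 0.20). Of 7 jasmonate genes 3 rose and 1 fell (2 and 1 over the list alone; camera adjusted p = 0.88). EDS5 stood at 1.12 ± 0.237 CPM and DREB2A at 94.8 ± 7.26. The 6 embryo and seed maturation regulators split into 2 that rose, 2 that fell and 2 that did not pass (camera adjusted p = 0.88).

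The largest rises in the labelled triple mutant outside these lists were those of VIM5 (648-fold [counting interval 179 to 5360]), the small peptide gene RTFL21 (AT1G67265) (601-fold [counting interval 107 to 23800]) and the blue copper protein gene BCB (AT5G20230), from 2.94 ± 1.11 to 1160 ± 191 CPM. Others were the dark-induced gene DIN11 (AT3G49620) (221-fold) and the cell wall enzyme gene XTH25 (AT5G57550) (205-fold). Among them was BCAT2 (AT1G10070), of branched-chain amino acid breakdown, from 2.31 ± 0.566 to 410 ± 69.3 CPM. The largest falls included the glycosyl hydrolase gene GH9B8 (AT2G32990) (219-fold), the cytochrome P450 gene CYP82C4 (AT4G31940) (263-fold [counting interval 47 to 10400]) and the sulfur deficiency gene ATSDI1 (AT5G48850) (195-fold). The auxin transporter gene PIN5 (AT5G16530) (184-fold [counting interval 32.8 to 7310]) fell as well, as did AOP2 (AT4G03060), of glucosinolate side chains (124-fold). Ribosomal RNA and reference genes moved with these groups. The ribosomal share was 1.40% ± 0.366 against 0.294% ± 0.0684 in WT. Of the 6 reference genes 4 rose and 0 fell, with UBQ10 (AT4G05320) at 3160 ± 550 CPM against 1280 ± 54.9 and ACT2 (AT3G18780) at 1360 ± 148 against 794 ± 62.3 (4 and 1 under upper-quartile scaling).

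In the labelled triple mutant 14386 of 20477 genes changed, 7078 higher and 7308 lower (edgeR quasi-likelihood, adjusted p under 0.05), and 7742 by at least 1 on the log2 scale (3435 higher and 4307 lower). The groups did not overlap in 72.8% of genes, against 10% by chance. Upper-quartile scaling moved the median of all genes by -0.177 and the split to 5789 higher and 8707 lower, so that 39.9% of the calls were higher in place of 49.2%. With offsets for GC content and length 7326 were higher and 6910 lower. These 3 libraries were made with the other RNA kit, and this comparison by itself does not separate the kit from the genotype. For EBS the kit alone is excluded, since it was as low in the labelled double mutant, with the kit of WT, and stood at 24.1 ± 1.49 CPM in emf1, with the kit of the labelled triple mutant.

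The comparison of emf1 with WT asked which transcripts differ in emf1. Of the floral identity genes PI rose from 3.09 ± 0.608 to 158 ± 18.6 (SD, n = 3; 50.9-fold). FUL (AT5G60910), a regulator of flowering and fruit, fell from 1.15 ± 0.171 to 0.0797 CPM (14.5-fold [counting interval 4.71 to 72.4]), while AG stood at 0.329 ± 0.283 CPM without passing the test. PAP85 rose to 21.8 ± 5.53 CPM (262-fold) and M17 to 33.7 ± 14.2. The MADS-box flowering genes AGL24, AGL42 and AGL14 (AT4G11880) fell, AGL24 to 1.27 ± 0.409 CPM and AGL14 from 4.18 ± 0.991 to 0.0486 (79.2-fold [counting interval 21.6 to 658]). The root iron genes IRT1 and NAS2 (AT5G56080), a nicotianamine synthase gene, and AGP30 had no count in emf1 and were at least 353-fold, at least 144-fold and at least 78.7-fold lower.

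By list, 6 of 14 floral identity genes rose and 1 fell in emf1 (6 and 1 over the list alone; camera adjusted p = 0.076). Of 22 flowering time genes 6 rose and 7 fell (6 and 7 over the list alone; camera adjusted p = 0.52). Under upper-quartile scaling 5 flowering time genes rose and 11 fell. The flowering repressor gene TEM1 (AT1G25560) was among those that rose, from 33.8 ± 16.3 to 217 ± 52.7 CPM. Of 18 root tissue markers 15 fell and 0 rose (15 and 0 over the list alone; camera adjusted p = 4e-04, and adjusted p = 0.60 with an estimated correlation), with the root hair genes COBL9 (AT5G49270) and LRX1 at 0.0971 ± 0.168 and 0.22 ± 0.316 CPM against 3.31 ± 0.767 and 6.67 ± 2.08. Of 13 flavonoid and anthocyanin genes 12 fell and 0 rose (12 and 0 over the list alone; camera adjusted p = 0.016, and adjusted p = 0.60 with an estimated correlation). DFR stood at 0.719 ± 0.891 CPM and LDOX at 0.705 ± 1.16. Of 19 abscisic acid, cold and drought genes 2 rose and 9 fell (camera adjusted p = 0.33), with the cold gene COR15A (AT2G42540) at 2.25 ± 3.67 CPM against 29.7 ± 12.9. Of 7 jasmonate genes 0 rose and 3 fell (camera adjusted p = 0.39), with VSP1 and VSP2 at 0.209 ± 0.0281 and 0.447 ± 0.0618 CPM. Of 12 salicylic acid genes 3 rose and 5 fell (camera adjusted p = 0.39), and of 11 meristem genes 1 rose and 5 fell (camera adjusted p = 0.63). Seed storage genes and embryo regulators each had 2 members higher and 2 lower, Polycomb group genes 4 and 3 (3 and 1 over the list alone), and anther markers 0 and 2 (1 and 2 over the list alone).

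Of 36 photosynthesis genes 19 were higher and 3 lower in emf1, and the list was not called (19 and 3 over the list alone; camera adjusted p = 0.061), while 10 were higher and 4 lower under upper-quartile scaling. The Rubisco activase gene RCA (AT2G39730) rose from 8770 ± 266 to 15700 ± 1960 CPM, and RBCS2B fell to 1680 ± 361. Of 8 touch and wounding genes 7 rose and 0 fell (7 and 0 over the list alone; camera adjusted p = 0.11), with TCH3 at 362 ± 114 CPM and ZAT12 (AT5G59820) at 28.1 ± 8.2 against 3.93 ± 0.171 in WT. Large rises were also seen for BCB (572 ± 213 CPM), BCAT2 (98.2-fold) and DIN11 (148-fold). They were also seen for the efflux carrier gene DTX1 (AT2G04040) (0.571 ± 0.245 to 57.5 ± 7.53 CPM) and the small heat shock protein gene HSP17.6A (AT5G12030) (99.8-fold). Large falls were those of the glucosinolate genes AOP2 (194-fold) and FMO GS-OX3 (AT1G62560) (64.7 ± 8.82 to 0.291 ± 0.505 CPM) and of MLP28 (AT1G70830) (168 ± 14.9 to 0.812 ± 0.832 CPM). The ribosomal RNA share was 0.703% ± 0.118 here. Of the 6 reference genes 4 rose and 0 fell, or 4 and 2 under upper-quartile scaling, with ACT2 at 2100 ± 199 CPM against 794 ± 62.3 in WT.

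In emf1 13231 genes changed, 6284 higher and 6947 lower (edgeR quasi-likelihood, adjusted p under 0.05), and 6618 by at least 1 on the log2 scale (2260 higher and 4358 lower). The groups did not overlap in 68.6% of genes, against 10% by chance. Upper-quartile scaling moved the median of all genes by -0.17 and gave 4796 higher and 8398 lower genes, 36.3% higher in place of 47.5%. More genes were higher than lower without ribosomal RNA loci (6885 and 6452), with offsets for GC content and length (6949 and 6348), with a filter of 1 CPM (6760 and 6259) and without WT replicate 2 (6531 and 6170). The emf1 libraries, too, differ from WT in the RNA kit as well as in the genotype.

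The labelled triple mutant and emf1 shared the RNA kit, and their comparison asked where libraries of these labels differ. Among the genes higher in the labelled triple mutant were PI, at 347 ± 39.5 against 158 ± 18.6 CPM, SEP2, at 14.2 ± 5.4 against 0.71 ± 0.974, and AP3, at 12.4 ± 10.3 against 0.68 ± 0.356 (SD, n = 3). Of 14 floral identity genes 10 were higher and 0 lower (11 and 0 over the list alone; camera adjusted p = 1.3e-05, and adjusted p = 0.26 with an estimated correlation). Of 22 flowering time genes 11 were higher and 2 lower (11 and 2 over the list alone; camera adjusted p = 0.00061, and adjusted p = 0.055 with an estimated correlation). Among them were AGL24 (13.1 ± 1.99 against 1.27 ± 0.409 CPM) and AGL19 (AT4G22950) (5.73 ± 1.51 against 0.406 ± 0.199). All 34 photosynthesis genes past the threshold, of 36, were lower in the labelled triple mutant (0 higher and 35 lower over the list alone; camera adjusted p = 1.9e-11, and adjusted p = 0.43 with an estimated correlation). The Rubisco small subunit gene RBCS1B (AT5G38430) stood at 739 ± 212 against 2480 ± 491 CPM.

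Of 7 jasmonate genes 4 were higher and 0 lower in the labelled triple mutant than in emf1 (camera adjusted p = 0.12), with VSP1 at 8.22 ± 7.91 against 0.209 ± 0.0281 CPM. Of 7 seed storage and late embryogenesis genes 5 were higher and 1 lower (camera adjusted p = 0.10), with EM1 at 2.29 ± 1.35 CPM and no count in emf1. Of 19 abscisic acid, cold and drought genes 7 were higher and 2 lower (9 and 2 over the list alone; camera adjusted p = 0.10), with the cold gene COR47 (AT1G20440) at 393 ± 66.2 against 112 ± 13.1 CPM. CRK4, ARI3 (AT3G27710) and the MADS-box gene AGL17 (AT2G22630) were among the higher genes with the largest ratios, at 54.3 ± 17.6 against 0.336 ± 0.314, 5.75 ± 1.87 against 0.0296 and 11.8 ± 1.49 against 0.156 ± 0.147 CPM. The sulfotransferase gene ST4C (AT1G13430) (0.0316 against 9.59 ± 1.71 CPM), SRF8 (0.552 ± 0.0213 against 12.4 ± 1.97), the serine acetyltransferase gene SERAT3;2 (AT4G35640) (0.466 ± 0.183 against 5.78 ± 1.1) and EBS were lower. Reference genes differed here as well, with UBQ10 higher and ACT2 lower in the labelled triple mutant. In total 9022 genes differed, 4829 higher and 4193 lower (edgeR quasi-likelihood, adjusted p under 0.05), and 3078 by at least 1 on the log2 scale (2088 higher and 990 lower). When only these 2 genotypes were fitted the count was 6385, and 70% of the 9022 calls were kept. More genes were lower than higher without ribosomal RNA loci (4303 higher and 4770 lower), with a filter of 1 CPM (4245 and 4724) and without labelled triple mutant replicate 1 (3987 and 4301) or 2 (3797 and 4227). The groups did not overlap in 48.0% of genes, against 10% by chance.

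The interaction asked whether the difference between lhp1 and WT equals that between the labelled triple mutant and the labelled double mutant. Floral identity genes were among those that differed. AG rose from 0.0824 to 22.9 ± 2.76 CPM between WT and lhp1, and stood at 3.57 ± 1.53 in the labelled double mutant and 3.57 ± 2.69 in the labelled triple mutant. SEP3 rose from 1.33 ± 0.285 to 133 ± 9.88 CPM in the first pair and was at 117 ± 15.2 and 17.2 ± 12.5 in the second. AP1 stood at 0.0204 and 2.2 ± 0.579 CPM in the first pair and 11.3 ± 1.96 and 0.709 ± 0.51 in the second. Of 14 floral identity genes 13 had a negative interaction and 0 a positive one (14 and 0 over the list alone; camera adjusted p = 2.3e-13, and adjusted p = 0.031 with an estimated correlation). Of 11 meristem genes 7 had a negative interaction and 0 a positive one (camera adjusted p = 0.11), with CUC3 at 0.983 ± 0.0684, 1.86 ± 0.243, 4.21 ± 0.73 and 0.542 ± 0.0615 CPM in the same order. The wax synthase gene WSD1 (AT5G37300) stood at 0.901 ± 0.271, 9.11 ± 3.59, 14.7 ± 1.98 and 0.115 ± 0.146 CPM, and the lectin gene JAL23 (AT2G39330) at 0.225 ± 0.0672, 2.36 ± 1.25, 11.4 ± 3.01 and 0.116 ± 0.0627.

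Genes with a positive interaction included BCB, the asparagine synthetase gene ASN1 (AT3G47340) and the dark-induced gene DIN2 (AT3G60140), with ASN1 at 94.4 ± 99.6, 43.3 ± 37.9 and 47.9 ± 32.3 CPM in WT, lhp1 and the labelled double mutant and 1850 ± 540 in the labelled triple mutant. Of 8 touch and wounding genes 5 had a positive interaction and 0 a negative one (camera adjusted p = 0.073), of 18 root markers 1 and 10 (camera adjusted p = 0.053), and of 6 reference genes 4 and 0 (camera adjusted p = 0.083). The camera calls that held with an estimated correlation were those of the floral identity, flowering time and seed storage lists in lhp1, of these and the meristem list in the labelled double mutant, and of the floral identity list in the interaction. In total 11645 genes passed the threshold, 5447 with a positive and 6198 with a negative interaction (edgeR quasi-likelihood, adjusted p under 0.05). Upper-quartile scaling moved the median of all genes by -0.175 and the split to 4291 and 7385, 36.8% positive in place of 46.8%, while offsets for GC content and length gave 5794 positive and 5602 negative. Of the 4 genotypes in this term only the labelled triple mutant had the other RNA kit, so the term includes any effect of the kit, and fitted values of genes near 0 counts are not ratios of levels.

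Calls were compared between mutants, all of which share the 3 WT libraries. Of the 269 genes changed in lhp1, 185 changed the same way in the labelled double mutant and 7 the opposite way. Of the shared calls 130 were higher and 55 lower in both, where independent lists would share 8.4 and 2.8. Their log2 fold changes over all genes had a Pearson r of 0.62 (0.50 in simulated data in which no gene differed and the comparisons shared WT libraries) and a covariance of 0.24 (0.038 simulated). The labelled triple mutant shared 1169 of the 1604 calls of the labelled double mutant in direction and had 130 opposite. Of these shared calls 797 were higher and 372 lower, against 376.1 and 184.2 for independent lists (r of 0.48, 0.49 simulated; covariance of 0.62, 0.038 simulated). The labelled triple mutant and emf1 shared 9985 calls in direction and had 612 opposite. Here 4706 were higher and 5279 lower in both, against 2172.1 and 2479.3 for independent lists (r of 0.80, 0.48 simulated; covariance of 2.25, 0.038 simulated). Of the calls of the labelled double mutant 721 had the same and 372 the opposite direction in emf1 (457 higher and 264 lower in both, against 333.9 and 175.1; r of 0.21, 0.49 simulated; covariance of 0.25). Of the lhp1 calls 94 had the same and 81 the opposite direction in emf1 (46 and 48, against 48.5 and 37.7; r of 0.05, 0.49 simulated; covariance of 0.05, 0.039 simulated). lhp1 and the labelled triple mutant shared 167 calls and had 51 opposite (107 and 60, against 54.6 and 39.6; r of 0.19, 0.49 simulated; covariance of 0.18). The simulated comparisons shared 0 calls, which follows from their setting, since no gene differed in them. Their r came from the shared WT libraries alone. An r below the simulated one therefore does not show that 2 mutants agree less than unrelated ones. The 3 WT libraries were not divided between the comparisons, since 1 comparison would have been left with 1 of them, so part of an excess may come from the shared WT libraries. In the pair of labelled triple mutant and emf1 part may come from the shared kit.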

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

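The test of the RNA kit was chosen after the results were seen. The other tests were written down before their values were computed, though GI was known among the clock genes and the excess of calls in the block that holds SHL had been seen when the test of a linked segment was chosen.

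The difference between lhp1 and WT was not that between the labelled triple mutant and the labelled double mutant in 11645 genes by the test of the interaction, and this difference between groups is what brought the following results here. It is not shown to be an effect of the lhp1 mutation in the background of the labelled double mutant, because LHP1 stood at 21.1 ± 2.07 CPM in the labelled triple mutant, against 19.8 ± 1.15 in WT and 10.5 ± 0.384 in lhp1 (SD, n = 3). Among genes that met the naming rule, the largest positive fitted log2 values were those of VIM4 (7.28), BCB (6.62), ASN1 (6.39), DIN2 (6.06) and CRK13 (5.92). The largest negative ones were those of WSD1 (-10.27), AP1 (-10.22), JAL23 (-9.92), SEP3 (-9.41) and AP3 (-8.46). AP1 and AP3 were near 0 counts in WT, so their fitted values are not ratios of levels and their ranks are uncertain. WSD1 and JAL23 were near 0 counts in the labelled triple mutant, so the size and rank of their values are uncertain as well. The call of VIM4 was lost without WT replicate 3 (adjusted p = 0.0822). The floral identity list differed as well (camera adjusted p = 2.3e-13). The labelled triple mutant alone among these 4 genotypes had the other RNA kit, so an effect of the kit, if there is one, is included in these values.

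In the labelled triple mutant and emf1, 7 of 8 touch and wounding genes rose, in a list that was not called (camera adjusted p = 0.14 and 0.11), and so did all 13 starvation genes, a list chosen after the data were seen and not tested for enrichment. An other hour of harvest predicted that morning and evening clock genes would move apart by at least 1 in both genotypes, and the evening median lay above the morning median by 2.61 in the labelled triple mutant and by 1.37 in emf1 (-0.28 in lhp1 and 0.16 in the labelled double mutant), as that explanation predicted. The morning genes did not all move, with CCA1 at 142 ± 15.3 CPM in WT, 41 ± 5.89 in the labelled triple mutant and 144 ± 24.4 in emf1 (SD, n = 3). In emf1, 2 of 4 morning genes fell and 2 of 5 evening genes rose, without TOC1 (log2 fold change 0.08). The evening median there, 0.75, was the value of ELF4, a gene at 0.264 CPM in WT and 0.462 in emf1. Both genotypes also had the other kit. An effect of the genotype or the kit on clock genes would meet the same prediction, so this test does not single out the hour. For the RNA extraction kit, the lowest library of the second kit lay 2.09 log2 units above the highest of the first in the median of the starvation genes. These genes were chosen after their rise was seen. For the touch genes, fixed beforehand, the lowest library of the second kit was at 1.95 and the highest of the first at 1.42. Since no genotype was extracted with both kits, the kit and the genotype cannot be told apart. No biological explanation was tested.

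LHP1 stood at the WT level in the labelled triple mutant, and below the 26.3 ± 1.34 CPM (SD, n = 3) of emf1, which had the same RNA kit. Reads of the overlapping gene AT5G17680 would have had to rise by at least the 9.31 CPM that LHP1 lost in lhp1, and that gene changed by -1.3 CPM (SE 0.4, n = 3 per group), which argues against this explanation. That the libraries do not carry the lhp1 mutation could not be examined, since only 1 of 40 neighbours of LHP1 was called in lhp1 (the same gene was called the same way in the labelled triple mutant against the labelled double mutant), and 3 were needed. Between these 2 genotypes 13931 of 20477 genes were called, 6721 of them higher in the labelled triple mutant, so 1 shared call does not speak for the mutation. An allele whose transcript stays at the WT level in this background may be the biological alternative, and the labels give no allele.

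Calls of the labelled double mutant were in excess at the end of chromosome 4, in a block that holds SHL but is not centred on it. Of 104 blocks of neighbouring genes tested for chromosome segments from another parent, 1 held more calls than chance, the last of chromosome 4, with 30 calls among 116 genes where 9.1 were expected (hypergeometric adjusted p = 3.7e-07). In the labelled triple mutant and emf1 most tested genes were called, so that an excess there could hardly show. A segment linked to the shl mutation predicted that the calls in the block would recur more often in the labelled triple mutant against emf1, and 48.3% (14 of 29) did, against 61.3% (965 of 1574) outside the block (Fisher's exact test, p = 0.18). A share inside at or below that outside was the outcome set beforehand for no linked segment, and the shares met it. Their difference was not past the test's threshold, so a segment could neither be shown nor excluded, and no biological explanation was tested.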

How the results depend on the processing

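Settings without ribosomal RNA loci and with GC and length offsets were tests chosen after the data were seen; the others were fixed beforehand. Of 150 values of the main counts under an alternative, 119 stayed within 1.5 times and 31 moved. Of 6053 values for named genes, 5797 stayed called, in the same direction, or stayed uncalled. Another 254 lost the call, 1 gained it (LHCB1.3 in lhp1, adjusted p = 0.0413 with DESeq2) and 1 called value turned. Of 360 list values 313 stayed, 16 lost and 31 gained a call. Changes of direction between values that were both uncalled were counted as unchanged, for genes and for lists. The value that turned was the log2 fold change of EMF1 in emf1, 0.005 with GC and length offsets (adjusted p = 0.957); the cause was not tested.

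For lhp1 the count of 269 became 471 with only the groups compared and 507 with DESeq2 (cause not tested), and 120 at an adjusted p under 0.01. For the labelled double mutant 1604 became 796 at that threshold and 2342 with only the groups compared. That fit, which does not take in the spread of other genotypes, lowered the counts of the labelled triple mutant, emf1 and their comparison to 13063, 11721 and 6385. At an absolute log2 fold change of at least 1 the counts were 907 for the labelled double mutant, 7742 for the labelled triple mutant, 6618 for emf1, 3078 for the labelled triple mutant against emf1 and 6994 for the interaction, and the shared calls were 56 (lhp1 and emf1), 624 (the labelled double mutant and labelled triple mutant), 341 (the labelled double mutant and emf1) and 5055 (labelled triple mutant and emf1), by construction fewer. Lists called fell from 5, 7, 4, 2 and 3 to 3, 4, 0, 0 and 0 with an estimated correlation in lhp1, the labelled double mutant, the labelled triple mutant, emf1 and the labelled triple mutant against emf1, and stayed at 1 in the interaction; fry called 9, 13 and 7 in the last 3 of these and 10 in the interaction, testing each list by itself rather than against other genes.

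Leaving out 1 library gave 144 to 209 genes for lhp1, 950 to 1119 for the labelled double mutant, 13442 to 13943 for the labelled triple mutant, 12096 to 13003 for emf1, 7875 to 8598 between these 2 and 10647 to 11502 for the interaction; fewer libraries give fewer calls. The replicate number as a block gave 207, 1354, 14157, 12923, 8593 and 11298. Libraries of the same number correlated at -0.333 to 0.175 (mean -0.0521, 3 of 30 pairs over 0.1) and others at -0.325 to 0.287 (mean 0.0258, 60 pairs), and 0 of 15 correlated best with their own number in every other group, so the numbers were not treated as pairs. Depth limits ratios over groups with few counts; those over no count are given as bounds and those over 1 to 3 counts with counting intervals.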

Other observations

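The gene groups in this paragraph were chosen after the data were seen. All 13 dark and sugar starvation genes rose in the labelled triple mutant and in emf1, with median log2 fold changes of 4.29 and 3.53, and 0 rose in lhp1 and 2 in the labelled double mutant. SEN1 stood at 38 ± 31.9 CPM in WT, 1200 ± 207 in the labelled triple mutant and 718 ± 343 in emf1 (SD, n = 3), DIN10 at 188 ± 215, 4430 ± 851 and 3410 ± 1270, and the trehalose phosphate synthase family gene TPS8 at 186 ± 148, 581 ± 67.9 and 766 ± 81. All 7 root hair genes fell in both genotypes (medians -3.47 and -4.03), and so did 3 and 4 of 5 root endodermis genes (-0.99 and -1.34), with CASP1 at 11.4 ± 0.926 CPM in WT, 3.1 ± 2.01 in the labelled triple mutant and 2.32 ± 0.66 in emf1. Both root groups are parts of the root tissue marker list above, so their falls repeat those of that list and add no separate evidence. Of 4 nuclear ribosomal RNA loci 4 and 3 rose (2.04 and 1.65). Of the morning clock genes 4 and 2 of 4 fell, and of the evening clock genes 3 and 2 of 5 rose. LHY stood at 141 ± 24.6 CPM in WT, 25.5 ± 7.56 in the labelled triple mutant and 66.3 ± 20.3 in emf1, and TOC1 at 13.7 ± 1.44, 29.7 ± 2.44 and 14.5 ± 3.63.

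In single libraries, the median log2 level of the starvation genes over the WT mean was 3.75 to 4.58 in the labelled triple mutant, 3.05 to 4.2 in emf1 and -0.92 to 0.96 in the other 9 libraries. That of the touch genes was 1.95 to 4.17, 2.6 to 3.13 and -1.15 to 1.42, the last in labelled double mutant replicate 1.

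The tests of other splits of the libraries were written down before their values were computed. In fits of the 2 groups alone, the real grouping called 471 genes for lhp1, 2342 for the labelled double mutant, 13063 for the labelled triple mutant, 11721 for emf1 and 6385 for the labelled triple mutant against emf1, and the highest of the other splits called 0 in each. The real split was 1 of 10 splits in each, and 10 splits are too few for a share under 0.05. Each other split mixed libraries of both genotypes within its groups, which widens the spread there and lowers the number called. The 0 of these splits is therefore not the number that like libraries would give. For the interaction the real split, with 11970 genes, was the highest, 1 of 100 splits. The 3 of 99 other splits that kept the libraries of the labelled triple mutant together called 10551 to 11206 genes and the rest at most 4, so the count follows the place of these 3 libraries.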
